A study of Mus musculus with 33 samples.

How the data were processed

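The material was RNA from cultured CD-1 mouse motoneurons and from NSC34 cells, in 33 libraries of 15 groups. Per the labels, total RNA of the axonal and somatodendritic compartments of microfluidic chambers gave 22 RNA-seq libraries, and 11 libraries came from iCLIP with antibodies 1 and 2 against hnRNP R or with IgG. The treatment field of the labels reads none, and how the knockdowns were made is not given in the sources used here. Extraction followed published protocols cited in the labels.

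The authors' RNA values came as 4 comparison tables, 1 per knockdown and compartment, each holding 37926 records on build GRCm38. The FPKM values were made by the authors with Cufflinks 2.2.1 after quality control with FastQC 0.10.1, per the labels, as 1 value per group scaled within each table. The log2 fold changes in the deposited tables are knockdown over GFP control. The score of each gene is the authors' test statistic in the deposited tables. Each p-value and q-value was computed by the authors and deposited as such, with a smallest p-value of 5e-05. The q-values were checked against Benjamini-Hochberg over the tested genes and differed by at most 5.28e-07. Aligner, annotation release and the settings of the authors' test are not given in the sources used here. The authors tested 1749 and 1009 genes in axons (hnRNP R, then 7SK) and 2768 and 1954 on the somatodendritic side. The lowest FPKM of the higher group among tested genes was 21.8, 35.5, 20.9 and 27.0 in that order, so genes under these levels carry no test. The locus Gm26924 alone held between 36.8% and 47.5% of the summed FPKM of a group. Some records merge several neighbouring genes (91, 55, 124 and 97 of the tested), and these share 1 value. Group values without replicates allow no refit, so no paired, blocked or per-replicate test of the RNA data was possible.

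The iCLIP values were deposited as a count of cDNAs per gene and library, with 1 library per file. The files name build mm9 and Ensembl release 59, per the file headers, and sum each cDNA count over a gene and its parts. Trimming, aligner and the collapsing of identical reads are not given in the sources used here. Counts were whole numbers, and no coordinates were moved between builds. Genes of both data types were joined by name. Of 36194 iCLIP genes 19104 (52.8%) matched exactly, 3089 (8.53%) by an identifier in the name, 1604 (4.43%) by a synonym and 55 by another case, and 12342 (34.1%) had no match. A further 1221 per-sample columns of the iCLIP data were not used here. The header of the IgG library names hnRNP R as its protein and shares a library number, 14, with NSC34 replicate 2, so its identity rests on its title.

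For the RNA comparisons a gene was called at the authors' q under 0.05 with a completed test. Gene lists (28 and the 2 targets) were written before the data were examined, as were the comparisons, the tests and most alternatives. Each list was described by its calls over all genes, by its calls with Benjamini-Hochberg adjusted over the list alone from the authors' p, and by the percentile of its median log2 ratio among 10000 random lists matched on FPKM in 10 bins. A percentile was given where at least 3 members were tested. Marker lists of other cell types were also read over all members with a value. Of the microglia list, 12 of 15 genes were at 1 FPKM or more in the somatodendritic control and 0 were in another list; for fibroblast markers 8 of 16, for astrocyte markers 15 of 16, for oligodendrocyte markers 12 of 17 (1 in another list), for endothelial markers 3 of 14 and for markers of other neurons 12 of 17.

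Overlaps between knockdowns were counted per direction among genes tested in both tables and set against independent lists. The planned one-sided Fisher's exact test was run, but its p is not given, because it assumes lists with separate controls. Both knockdowns share their controls. Thus 1000 simulated pairs of unchanged groups with common controls gave the overlap, correlation and covariance that sharing produces where no gene changes. The difference of a knockdown effect between compartments used an approximate z test, with each standard error taken from the authors' p, and Benjamini-Hochberg over genes tested in both compartments. Control levels of axons and cell bodies were set side by side as log2 ratios with 0.1 FPKM added. No gene of these RNA tables was tested anew on replicates.

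The iCLIP counts were tested with edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling, the quasi-likelihood fit as this version runs it by default, and Benjamini-Hochberg at 0.05. Genes with at least 10 cDNAs over the libraries in a fit were kept. One fit of the 5 unfractionated libraries gave motoneurons against NSC34 cells and NSC34 cells against IgG, since the lone IgG library is assumed to vary like the others. Another fit of 6 libraries gave nuclear against cytoplasmic fractions with a block for each pair of the same cells and antibody. Pairing was read from the titles, and the deviations of the pairs correlated with Pearson 0.50, 0.12 and 0.11. Replicate numbers of motoneuron and NSC34 libraries gave -0.00681, so they were not taken as pairs in the test. DESeq2 1.42.0 served as the other tool. List enrichment among iCLIP calls (one-sided Fisher's exact test) and list counts under each scaling were added after planning. Shares have exact Clopper-Pearson intervals, and ratios against 1 to 3 cDNAs have counting intervals. A group at 0 was given a floor of 3 counts over the group. With 2796 cDNAs in the shallowest library, 1 cDNA is the smallest step that its shares can show. Genes most crosslinked were the top 10% by cDNAs of both unfractionated motoneuron libraries per FPKM, set against 10000 random sets matched on FPKM, and against genes with no cDNA by 10000 permutations of membership within FPKM bins.

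Genes were named by a rule written before the data were examined. Per knockdown comparison it names Hnrnpr and Rn7sk, the 10 highest and 10 lowest log2 ratios among called genes with FPKM above 0 in both groups and at least 1 in 1 group, and up to 4 members per list with the smallest p. Where fewer than 10 passed, the smallest p among unadjusted p under 0.05 filled the names and are said not to pass. For iCLIP it names the 10 highest and 10 lowest called genes with at least 50 cDNAs. Other names are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

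Alternatives changed 1 choice at a time: unadjusted p, q under 0.01, an absolute log2 ratio of at least 1, an FPKM filter of 1, a pseudocount of 1 FPKM, unmatched random lists, other scalings, DESeq2, other count minimums (1 and 50 cDNAs), no mitochondrial chromosome, crosslink positions in place of cDNAs, other sets of libraries, blocks, and leaving out each library. A bias-adjusted quasi-likelihood fit, the matching of all lists on locus span and the permutation against genes with no cDNA were added after the data were seen.

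The tests were run on simulated data. With changes of 4 and 2 on the log2 scale edgeR recovered 62.4% and 8.42% in the IgG design (9064 genes, false calls 1.49%), 90.5% and 67.0% in the motoneuron design (9061 genes, false calls 4.26%) and 0% and 0% in the design of fractions (4355 genes). The z test recovered 56.5% of differences of 1.5 among 1000 genes, with false calls of 4.24%. Of 200 simulated lists of 30 genes (2768 genes in all) with no shift, 0.5% lay above and 5.5% below the central 95%, and with a shift of 0.3 on the log2 scale 78% lay above. A simulated trend with locus span and no list effect put a list of 66 short genes at percentile 99.99 with FPKM matching alone and at 16.7 with span matched too, so all lists were also matched on both. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.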

Results

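The data describe mouse motoneurons in which either hnRNP R, an RNA-binding protein of the hnRNP family, or the noncoding RNA 7SK was knocked down, and the RNAs that hnRNP R contacts. 7SK is an abundant RNA that holds the elongation kinase P-TEFb in an inactive complex. Primary CD-1 motoneurons had been grown in microfluidic chambers, which let axons grow into a separate compartment, and RNA was taken from the axonal and from the somatodendritic side. The 22 RNA-seq libraries formed 6 groups. Control (GFP) and 7SK knockdown groups had 4 libraries each per compartment and hnRNP R knockdown groups had 3. The authors' deposited tables gave 1 FPKM value (fragments scaled to gene length and depth) per group, so no spread between these replicates was available here and the read depth is unknown. A further 11 libraries in 9 groups came from iCLIP, which counts cDNAs that end at positions where a protein was crosslinked to RNA by ultraviolet light. They covered primary motoneurons and NSC34 cells, a mouse motoneuron-like hybrid line, with antibodies 1 and 2 against hnRNP R and a control IgG. Total cDNAs ranged from 2796 in the cytoplasmic NSC34 library of antibody 2 to 456721 in replicate 1 of the unfractionated NSC34 libraries, and the IgG library held 36280. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

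The targeted RNAs were read first. Hnrnpr (GRCm38 chromosome 4, 136310942 to 136345981) stood at 27.2 FPKM in the control and 10.8 FPKM in the hnRNP R knockdown on the somatodendritic side, a log2 ratio of -1.33 that did not pass the test over all genes (q = 0.310) in the authors' deposited table. Its unadjusted p was under 0.05, and it passed when adjusted over the list of the 2 targets alone. On the axonal side Hnrnpr was listed at 9.93 and 3.98 FPKM, a log2 ratio of -1.32, and was not tested there in the authors' deposited table. Rn7sk, the 7SK gene (chromosome 9, 78175303 to 78175633), fell from 9104 to 6370.2 FPKM on the somatodendritic side of the 7SK knockdown (log2 ratio -0.52, q = 0.00407) in the authors' deposited table. In the axon group labelled 7SK knockdown Rn7sk was at 3508 FPKM against 2708 in control axons (log2 ratio 0.37, q = 0.594), a direction opposite to the label, again in the authors' deposited table. After hnRNP R knockdown Rn7sk rose on the somatodendritic side from 9892 to 13493 FPKM (log2 ratio 0.45, q = 0.00865) and stood at 2638 and 4545 FPKM in axons (log2 ratio 0.79, q = 0.566), per the authors' deposited table. Other small noncoding RNAs, a list without Rn7sk, had a median log2 ratio of 1.22 in the axon group labelled 7SK knockdown (5 of 7 tested higher). Their median was 0.86 in 7SK cell bodies (6 of 6 higher), 0.20 in hnRNP R cell bodies (5 of 5) and -0.39 in hnRNP R axons (3 of 6). Whether Rn7sk moved differently from these RNAs was not tested.

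Knockdown of hnRNP R changed 2 genes in axons. Mtx1, a metaxin of the mitochondrial outer membrane import machinery (chromosome 3, 89209081 to 89227088), rose 5.14-fold from 8.92 to 45.9 FPKM (q = 0.0437) in the authors' deposited table. Ppfia3, a liprin-alpha scaffold of the presynaptic active zone (chromosome 7, 45339126 to 45370583), fell by 1.98 on the log2 scale from 29.1 to 7.37 FPKM (q = 0.0437) in the same authors' deposited table. No other gene passed among 1749 tested. Among those that did not pass, the authors' deposited table gave Ucp2, a mitochondrial uncoupling protein, at 19.9 and 82.6 FPKM (q = 0.221) and Rps6kc1 at 9.42 and 48.9 FPKM (q = 0.221). On the lower side it listed Plk2, a polo-like kinase, at 61.2 and 16.7 FPKM (q = 0.131), Cald1, the actin-binding caldesmon, at 97.6 and 36.6 FPKM (q = 0.131) and the neuropeptide precursor Vgf at 39.8 and 12.1 FPKM (q = 0.187), as values of the authors' deposited table. At an unadjusted p under 0.05 the authors' test gave 110 higher and 52 lower genes, against 87.45 that chance would give in all, and the median log2 ratio of tested genes was 0.14.

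Ribosomal protein and respiratory chain genes stood high as groups in axons after hnRNP R knockdown, while translation factors did not (11 of 25 higher, median -0.028, percentile 5.965). Of 38 cytosolic ribosomal protein genes tested, 37 were higher, with a median log2 ratio of 0.61 at percentile 100 of random lists matched on FPKM. None passed, over all genes or adjusted over the list alone. The stalk proteins Rplp1 (105 and 249.7 FPKM, q = 0.221) and Rplp0 (340.4 and 665 FPKM, q = 0.396) were listed among them in the authors' deposited table. Nuclear-encoded respiratory chain genes showed a median of 0.50 (53 of 59 higher, percentile 100, no call over all genes or adjusted over the list alone), with Cox8a, a cytochrome oxidase subunit, at 221 and 505 FPKM (q = 0.221) and Ndufa3 at 12.5 and 53.7 FPKM (q = 0.221) in the authors' deposited table. Histone genes had a median of 1.29 (9 of 10 higher, percentile 99.99). Adjusted over the list alone, 3 of them rose, among them Hist1h1a at 22.9 and 71.3 FPKM (q = 0.221 over all genes) in the authors' deposited table. Small noncoding RNAs had a median of -0.39 over 6 tested genes (percentile 0.21) but 0.34 over 7 members at 1 FPKM or more, tested or not (percentile 82.25). Adjusted over the list alone 1 rose and 1 fell, with Rny1, a Y RNA, at 1391 and 629 FPKM (q = 0.355) and Rpph1, the RNA of RNase P, at 1347 and 2845 FPKM (q = 0.321) in the authors' deposited table. Genes of inherited motoneuron disease were all lower (7 tested, median -0.40, percentile 1.60). Markers of astrocytes and radial glia had a median of -0.30 over 7 tested genes (percentile 1.08) and -0.019 over 16 members with a value (8 higher, percentile 31.59). Over all members with a value, with 0.1 FPKM added, microglia markers lay at 0.80 (percentile 97.58, summed FPKM 18.7 and 38.2) in the authors' deposited table. Fibroblast markers lay at -0.85 (percentile 0.26), but their summed FPKM was 1578 in control and 1660 in knockdown axons. Motoneuron markers lay at -0.57 (percentile 3) and oligodendrocyte markers at 0.55 (percentile 94.19) in the authors' deposited table.

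In the axon group labelled 7SK knockdown 31 genes passed, 23 higher and 8 lower, among 1009 tested. Gpnmb, a membrane glycoprotein of phagocytes, rose 26.9-fold from 1.81 to 48.8 FPKM (q = 0.0252) in the authors' deposited table. Spp1, osteopontin (chromosome 5, 104435118 to 104441050), rose 11.7-fold from 9.78 to 114 FPKM (q = 0.00360) in the authors' deposited table. Dnase2a, a lysosomal nuclease, rose 27.1-fold from 4.10 to 111 FPKM (q = 0.00360) in the authors' deposited table. The lipid carrier Apoe, named because it was among the 10 highest in another comparison, rose from 63.1 to 324 FPKM (q = 0.00360) in the authors' deposited table. The largest ratios belonged to Gm10800, from 21.4 to 1490.0 FPKM (q = 0.00360), and its neighbour Gm10801, from 19.0 to 701 FPKM (q = 0.0120), in the authors' deposited table. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255336), fell by 1.62 on the log2 scale from 543 to 176 FPKM (q = 0.00360) in the authors' deposited table. Csrp1, a LIM protein, fell by 2.26 from 89.9 to 18.8 FPKM (q = 0.00360) in the authors' deposited table. The matrix protein Tnc fell by 1.73 (q = 0.0488), tropomyosin Tpm1 by 1.36 (q = 0.00360) and caldesmon Cald1 by 1.66 (q = 0.0262) in the authors' deposited table. The intermediate filament Nes fell by 1.65 (q = 0.00797), Igfbp2 by 1.62 (q = 0.0291) and Plk2 by 2.82 (q = 0.00360) in the authors' deposited table. Radil (log2 ratio 3.55), Zfyve19 (2.73), Jarid2 (2.67), Agbl5 (2.53) and the long noncoding RNA locus Rmst (2.51) completed the 10 highest in the authors' deposited table. Unadjusted p under 0.05 gave 137 higher and 46 lower genes against 50.45 by chance, and the median log2 ratio of tested genes was 0.23.

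Ribosomal protein genes were again high in the axon group labelled 7SK knockdown (30 of 32 higher, median 0.87, percentile 99.98). Rpsa, a small-subunit component, rose from 68.2 to 178 FPKM (q = 0.0161), the only call over all genes, and 7 rose when adjusted over the list alone, with Rpl32 at 158 and 391 FPKM (q = 0.0505), as the authors' deposited table gave them. Respiratory chain genes had a median of 0.69 (45 of 47 higher, percentile 99.81). Cox7b rose from 55.4 to 192 FPKM (q = 0.0383) in the authors' deposited table, and no member passed when adjusted over the list alone. Small noncoding RNAs had a median of 1.22 (7 tested, percentile 98.42), with 2 calls over all genes and 3 adjusted over the list alone. Rmrp, the RNA of RNase MRP, rose from 682 to 2792 FPKM (q = 0.00360) and Rpph1 from 1382 to 4505 FPKM (q = 0.00360) in the authors' deposited table. Histone genes lay at 1.56 (5 of 5 higher, percentile 98.89, 1 adjusted over the list alone). Astrocyte and radial glia markers (8 tested, median -0.63, percentile 0.19) and fibroblast markers (5 tested, median -0.64, percentile 0.635) each held 1 gene that fell, over all genes and adjusted over the list alone, Nes and Acta2. Microglia and macrophage markers moved beside these groups: over 13 with a value the median log2 ratio, with 0.1 FPKM added, was 2.80, and the summed FPKM of the list was 19.2 in control axons and 183 in the axon group labelled 7SK knockdown. Over all members with a value, markers of other neurons lay at 0.77 (percentile 98.24) and motoneuron markers at -0.77 (percentile 1.54) in the authors' deposited table. Only Tyrobp of the microglia list was tested, at 0.886 and 43.0 FPKM (q = 0.236) in the authors' deposited table.

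**Figure D1:**
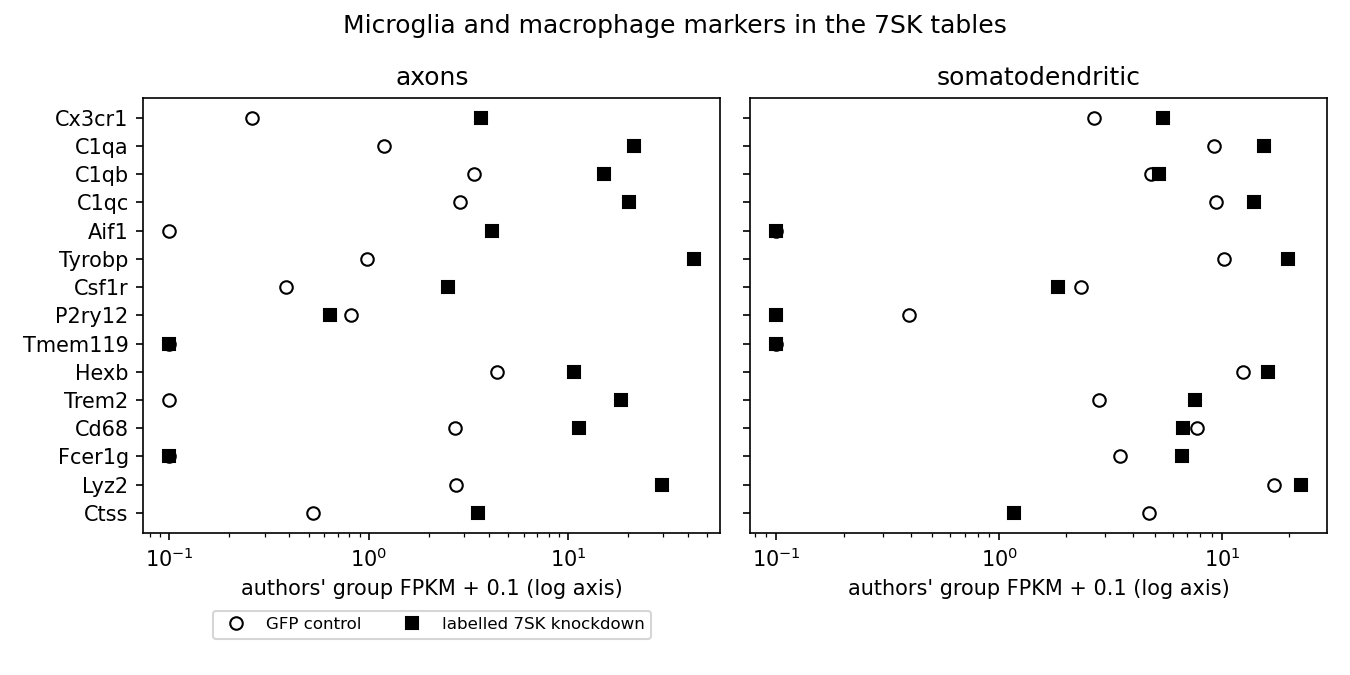
Group FPKM plus 0.1 (log axis, x) of each microglia and macrophage marker (y) in control (open circles) and labelled 7SK knockdown groups (filled squares), in axons (left) and on the somatodendritic side (right), 1 value per group and no error bars because the tables hold no replicates. Tyrobp stood at 0.886 and 43.0 FPKM in axons.

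On the somatodendritic side hnRNP R knockdown changed 27 of 2768 genes, 10 higher and 17 lower. The neuropeptide precursor Vgf (chromosome 5, 137030295 to 137033351) fell by 1.99 on the log2 scale from 36.8 to 9.27 FPKM (q = 0.00865) in the authors' deposited table. Nrep, a neuronal regeneration protein, fell by 1.51 from 94.6 to 33.1 FPKM (q = 0.00865) in the authors' deposited table. Slc6a5, the glycine transporter of inhibitory neurons, fell by 0.99 (q = 0.00865) in the authors' deposited table. H2-K1, a major histocompatibility class I molecule, had the highest ratio, 2.02-fold from 29.2 FPKM in the control (q = 0.0146), followed by Cdr1 (log2 ratio 0.92, q = 0.00865), in the authors' deposited table. Snn (0.75, q = 0.0252), the RNA-binding protein Celf4 (0.61, q = 0.0346), the synaptic vesicle protein Scamp5 (0.59, q = 0.00865) and Apoe (0.50, q = 0.0373) also rose in the authors' deposited table. The noncoding RNAs n-R5-8s1 (log2 ratio 0.54, q = 0.00865) and Rpph1 (0.38, q = 0.0198) rose as well in the authors' deposited table. Gmfb (-1.17, q = 0.0301), Zranb2 (-1.16, q = 0.0373) and the signalling adaptor Ywhaz (-1.14, q = 0.00865) were among the lowest in the authors' deposited table. So were the vesicle glycoprotein Sv2a (-0.86, q = 0.00865), March6 (-0.86, q = 0.00865), Camta1 (-0.85, q = 0.00865) and Hdlbp (-0.80, q = 0.0146) in the authors' deposited table. Unadjusted p under 0.05 gave 159 higher and 181 lower genes against 138.4 by chance.

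Of 26 presynaptic genes tested in these cell bodies 3 fell over all genes and 6 adjusted over the list alone. Their median of -0.15 lay at percentile 0.46, and over 37 members at 1 FPKM or more, tested or not, it was -0.064 (percentile 10.83). Sv2a was joined by Vamp1, a vesicle SNARE (49.3 to 28.6 FPKM, q = 0.00865), and Napb, a partner of SNARE disassembly (49.4 to 30.1 FPKM, q = 0.00865), in the authors' deposited table. Axonal cytoskeleton genes had a median of -0.12 (15 of 40 higher, percentile 0.03), and 1 fell, over all genes and adjusted over the list alone, namely Dpysl2, which regulates microtubules in growing axons (203 to 143 FPKM, q = 0.00865 in the authors' deposited table). Cholesterol synthesis genes had a median of -0.30 (2 of 12 higher, percentile 0.43) with no call over all genes or adjusted over the list alone, and -0.14 over 21 members at 1 FPKM or more, inside the central 95% (percentile 3.425). Ribosomal protein genes had a median of 0.18 (26 of 36 higher, percentile 99.68) with no call either way, and 0.13 over 70 members at 1 FPKM or more, also inside (percentile 97.25). Small noncoding RNAs had a median of 0.20 (5 tested, percentile 93.89) and 1 call, over all genes and adjusted over the list alone, Rpph1. Respiratory chain genes lay at -0.05 (59 tested, percentile 7.18) and histone genes at 0.01 (8 tested, percentile 51.09), but at -0.43 over 26 members at 1 FPKM or more, tested or not (percentile 0).

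Knockdown of 7SK changed 49 of 1954 genes on the somatodendritic side, 28 higher and 21 lower. The gene n-R5-8s1, a 5.8S ribosomal RNA copy, rose 6.63-fold from 2900.5 to 19234 FPKM (q = 0.00407) in the authors' deposited table. Gm24601 rose 10.8-fold from 224 to 2424 FPKM (q = 0.00407) in the authors' deposited table. The Y RNA Rny1 rose 2.35-fold from 1322 to 3106 FPKM (q = 0.00407), and the snoRNA host locus Gas5 rose by a log2 ratio of 1.42 (q = 0.00724), in the authors' deposited table. Rcc1, the exchange factor for the Ran GTPase, rose 3.86-fold (q = 0.00407), the translation initiation helicase Eif4a1 3.39-fold (q = 0.00888) and ribosomal protein Rps3 3.20-fold (q = 0.00407) in the authors' deposited table. Gm25360 (log2 ratio 1.94), Usp16 (1.89) and Atxn7l1 (11.3 to 32.0 FPKM) completed the 10 highest in the authors' deposited table. Kcnk9, a background potassium channel (chromosome 15, 72512119 to 72546279), fell by 2.26 on the log2 scale from 51.9 to 10.8 FPKM (q = 0.00407) in the authors' deposited table. Dner, a Notch ligand of neurons, fell by 1.42 (q = 0.00407) and the transcription factor Pbx3 by 1.11 (q = 0.00407) in the authors' deposited table. The surface protein Cd200 fell by 0.95 (q = 0.00407), Paip2 by 0.88 (q = 0.0409) and the Cluap1 locus by 1.06 (q = 0.0381) in the authors' deposited table. Unadjusted p under 0.05 gave 162 higher and 137 lower genes against 97.7 by chance.

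Of 40 axonal cytoskeleton genes tested in these cell bodies after 7SK knockdown 15 were higher and 25 lower (median -0.13, percentile 0.24), and 5 fell over all genes and 6 adjusted over the list alone. The neurofilament subunits Nefm (75.5 to 36.5 FPKM, q = 0.00407) and Nefl (85.6 to 54.9 FPKM, q = 0.0132), which share 1 annotated locus, and the microtubule-associated Dcx (45.6 to 26.2 FPKM, q = 0.00888) were among them in the authors' deposited table, with Map1b (-0.43) and Gap43 (-0.48) the others. Presynaptic genes included 2 that fell over all genes and 4 adjusted over the list alone (23 tested, median -0.10, percentile 4.41), among them Napb (log2 ratio -0.59, q = 0.0112) in the authors' deposited table. Ribosomal protein genes stood high as a group (31 of 32 higher, median 0.48, percentile 100), with 2 called over all genes, Rps3 among them, and 7 adjusted over the list alone. Small noncoding RNAs had a median of 0.86 (6 tested, percentile 99.85) with 4 that rose over all genes and 4 adjusted over the list alone, Rny1, Rny3, Rmrp (1902 to 3812 FPKM, q = 0.00407) and Rpph1 in the authors' deposited table. Histone genes lay at 0.54 (9 of 9 higher, percentile 99.65, 2 adjusted over the list alone). Translation factors included 2 that rose over all genes and 2 adjusted over the list alone, Eif4a1 and Eif4a2 (22 tested, median 0.15, percentile 89.88). Fibroblast markers (4 tested, median 0.65, percentile 98.82) included 2 that rose, over all genes and adjusted over the list alone, Acta2 (76.3 to 130.2 FPKM, q = 0.00407) and Fn1, fibronectin (23.3 to 33.7 FPKM, q = 0.00888), in the authors' deposited table. The astrocyte gap junction gene Gja1 rose from 18.6 to 36.2 FPKM (q = 0.00888 in the authors' deposited table), 1 of 7 astrocyte markers over all genes and adjusted over the list alone (median 0.20, percentile 85.48). With 0.1 FPKM added over all members with a value, oligodendrocyte markers lay at 0.96 (13 of 16 higher, percentile 99.93, summed FPKM 99.0 and 136), markers of other neurons at -0.50 (2 of 15 higher, percentile 0.29) and microglia markers at 0.41 (percentile 94.11) in the authors' deposited table. Markers of other neurons lay at -0.36 among tested genes (4, none higher, percentile 1.54) and respiratory chain genes at 0.11 (56 tested, percentile 86.5).

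**Figure D2:**
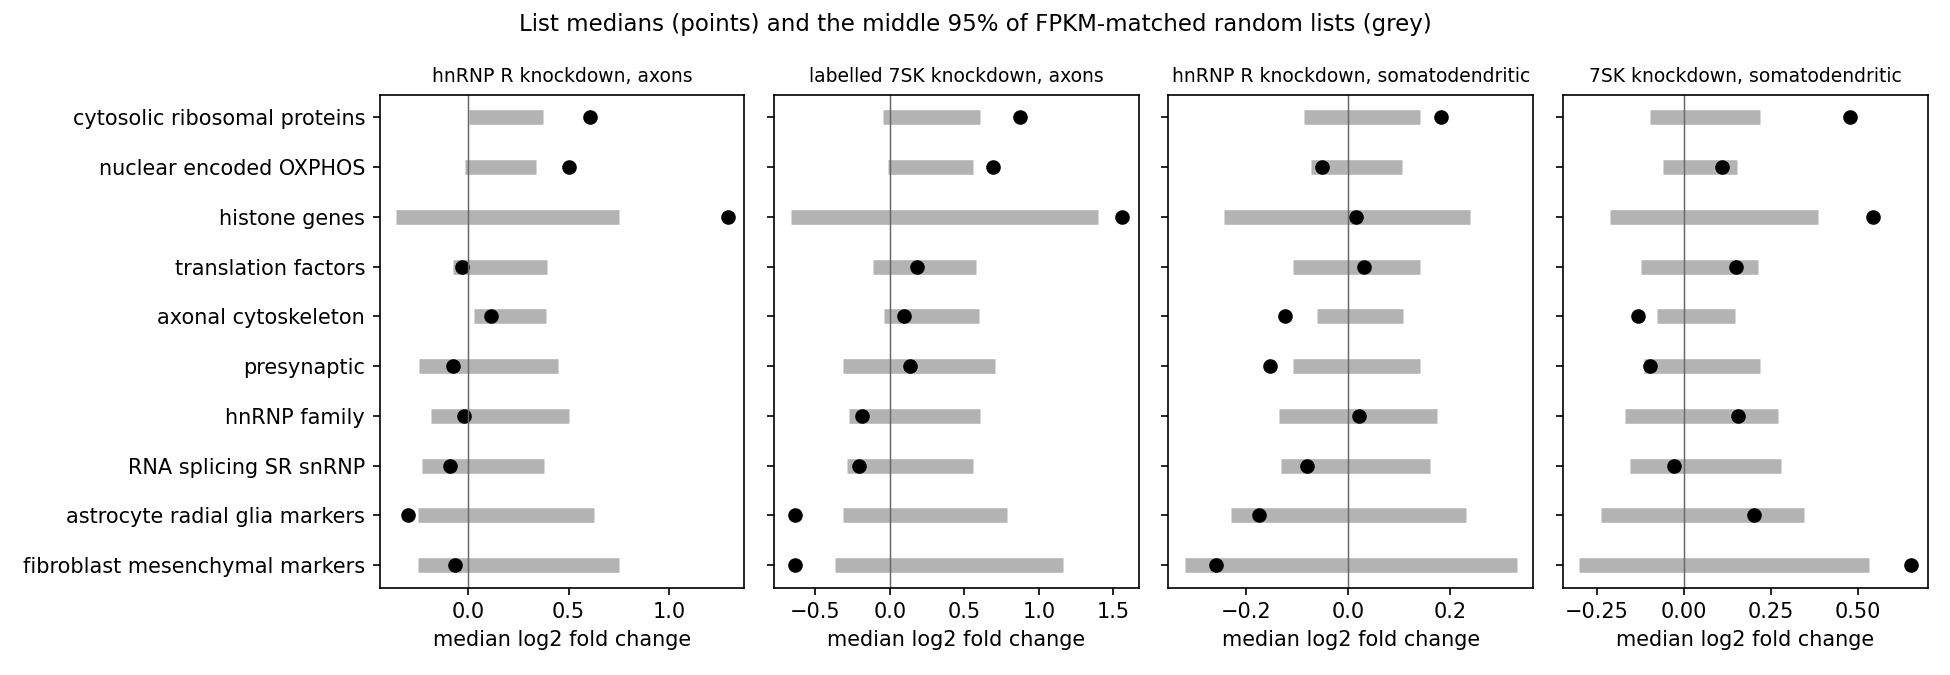
Median log2 fold change (x, its own scale in each panel) of the tested members of gene lists (y) in the 4 knockdown comparisons, with the central 95% range of 10000 random lists matched on FPKM as a line. The ribosomal protein median lay at percentile 99.68 or higher of its random lists in all 4 comparisons.

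Of 77 combinations of list and comparison with at least 3 tested members, 23 lay outside the central 95% of their random lists. Chance would put 3.85 there if genes and combinations were independent. Genes of a list can vary together and the comparisons share controls, so more can lie outside without an effect, and these percentiles only describe the lists. With random lists matched on locus span as well, chosen after the results were seen, 21 lay outside, 20 of them the same. Histone genes then lay inside in the axon group labelled 7SK knockdown (percentile 90.77) and in 7SK cell bodies (percentile 96.15), as did small noncoding RNAs in the former (percentile 93.9), and the unfolded protein response lay outside in hnRNP R axons (percentile 2.32). Other lists are given here in the order of hnRNP R axons, axons labelled 7SK knockdown, hnRNP R somatodendritic and 7SK somatodendritic. The hnRNP family had medians of -0.02, -0.18, 0.02 and 0.15, splicing factors -0.09, -0.21, -0.08 and -0.03, and genes of the mitochondrial genome 0.31, 0.88, -0.00 and 0.00. Proteins of the 7SK particle and P-TEFb had medians of -0.08, 0.08 and -0.07 where at least 3 were tested, leaving out the axon group labelled 7SK knockdown. Axonal cytoskeleton genes in axons had medians of 0.12 and 0.10, presynaptic genes -0.08 and 0.14, with 1 presynaptic gene that fell in the latter when adjusted over the list alone. Postsynaptic genes had medians of 0.23, -0.03 and -0.15 (hnRNP R axons, hnRNP R and 7SK somatodendritic), and axon guidance genes -0.12, 0.08 and -0.20 in the same order, with 2 genes of each falling in the 7SK somatodendritic comparison, and 1 guidance gene rising in the hnRNP R somatodendritic one, adjusted over the list alone. Translation factors lay at -0.03, 0.18 and 0.03 in the first 3 comparisons, and motoneuron disease genes at 0.14, 0.03 and 0.06 in the last 3, with 1 that rose in the last adjusted over the list alone. Cholesterol synthesis had 0.11, -0.47 and, on the somatodendritic side of 7SK, -0.20 (percentile 2.41), and the unfolded protein response -0.20, -0.01, 0.01 and 0.09. Nuclear long noncoding RNAs lay at 0.20, 0.07, -0.02 and -0.03, with 1 that rose in hnRNP R axons adjusted over the list alone. Targets of p53 lay at -0.47 and cell cycle genes at 0.21 in hnRNP R axons. Over all members at 1 FPKM or more, tested or not, the sign of the median turned for some of these lists. In hnRNP R axons the hnRNP family lay at 0.08, axon guidance at 0.02, cholesterol synthesis at -0.06, the unfolded protein response at 0.01, splicing factors at 0.0072 and nuclear long noncoding RNAs at -0.22. Translation factors lay at -0.02 in the axon group labelled 7SK knockdown, the 7SK particle at -0.15 and astrocyte markers at 0.20 in hnRNP R cell bodies, and splicing factors at 0.05 in 7SK cell bodies. Over the same members axon guidance (-0.20, percentile 0.12) and cell cycle genes (0.58, percentile 99.86) lay outside the central 95% in 7SK cell bodies, as did targets of p53 in hnRNP R axons (-0.40, percentile 1.67) and in the axon group labelled 7SK knockdown (-0.53, percentile 1.45). So did cholesterol synthesis in the axon group labelled 7SK knockdown (-0.30, percentile 1.28), fibroblast markers in hnRNP R axons (-0.48, percentile 1.70) and oligodendrocyte markers in hnRNP R axons (0.82, percentile 98.5) and cell bodies (0.52, percentile 99.23). Cholesterol synthesis in 7SK cell bodies then lay inside it (-0.037, percentile 14.005). Among tested genes, fibroblast markers lay at -0.06 in hnRNP R axons and -0.26 in hnRNP R cell bodies, where 1 fell adjusted over the list alone, and astrocyte markers at -0.18 there, with 1 that rose adjusted over the list alone. Other neurons' markers lay at 0.13 there. Slc6a5 fell, over all genes and adjusted over the list alone, and 1 more rose adjusted over the list alone. Motoneuron, oligodendrocyte, microglia, endothelial, immediate early and interferon lists had at most 2 tested members in any comparison and no call over all genes. Adjusted over the list alone, the chemokine Cxcl10 rose in hnRNP R axons (3.28 and 23.0 FPKM, q = 0.234 over all genes in the authors' deposited table). Tyrobp in the axon group labelled 7SK knockdown was the only tested member of its list, so this adjustment left its unadjusted p under 0.05 as it was.

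On the somatodendritic side H2-K1 (log2 ratios 1.02 and 1.01), n-R5-8s1 (0.54 and 2.73) and Rpph1 (0.38 and 0.44) rose in both and Napb fell in both (-0.71 and -0.59) in the authors' deposited tables. These were 3 shared of 10 and 26 higher calls among 1882 genes tested in both, where independent lists would share 0.138, and 1 shared of 13 and 21 lower calls, where they would share 0.145. Independent lists leave out the shared controls, whose effect on these calls was not simulated. At an unadjusted p under 0.05, 26 higher and 26 lower genes were shared there, where independent lists would share 6.72 and 10.4. Simulated unchanged groups that share the controls gave 8.09 and 7.99 (upper limit of the central 95% of simulations, 14 each). In axons no called gene was shared among 943 tested in both, because neither called gene of hnRNP R knockdown was tested in the other table. At an unadjusted p under 0.05 in both axon comparisons, 29 genes were higher and 7 lower, against 5.46 and 1.24 for independent lists and 3.97 and 3.84 in simulated unchanged groups (upper limits 9 and 8), so the lower genes stayed within the limit. Plk2 (-1.88 and -2.82), Ucp2 (2.05 and 1.75), Apoe (1.57 and 2.36) and Hist1h4d (1.53 and 1.74) were among them in the authors' deposited tables. The log2 ratios correlated across genes (Pearson 0.53 in axons, 0.40 on the somatodendritic side), where simulated unchanged groups gave 0.46 and 0.47. Their covariance was 0.220 in axons against a simulated 0.135 (upper limit 0.166) and 0.0719 against 0.0556 on the somatodendritic side, within the upper limit of 0.0730. Simulated unchanged groups call only the share of genes that chance gives at an unadjusted p under 0.05. The observed lists held 51 and 101 higher and 26 and 45 lower genes in axons (hnRNP R, then 7SK). On the somatodendritic side they held 91 and 139 higher and 143 and 137 lower genes. The simulated limits thus do not bound the overlap that shared controls give for longer lists. Genes are not independent replicates, and part of any excess may come from the shared control libraries.

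Whether a knockdown acted differently in the compartments was tested gene by gene. Acta2 was lower in the axon group labelled 7SK knockdown and higher on the somatodendritic side (difference of log2 ratios -2.39, SE 0.443, Benjamini-Hochberg adjusted p = 5.80e-05 by an approximate z test on the authors' deposited tables). Igfbp2 (-2.57) and Tpm1 (-1.70) differed in the same direction and the axonal kinesin Kif1a in the opposite one (1.53), all 4 named after their values were seen. They were 4 of 888 genes, against 106 at an unadjusted p under 0.05. With standard errors from the authors' test statistic 0 genes passed and 3 had an unadjusted p under 0.05. For hnRNP R the same z test called 0 of 1505 genes, with 105 at an unadjusted p under 0.05. The log2 ratios of the compartments correlated across genes with Pearson 0.29 for 7SK and 0.09 for hnRNP R.

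In the control groups the RNA levels of the axonal and the somatodendritic side were set side by side. Markers of fibroblasts and mesenchyme were higher on the axonal side (median log2 ratio 2.11, 14 of 16), with Fn1 at 237 FPKM in axons and 25.3 in cell bodies and the collagen Col1a1 at 26.3 and 2.74 FPKM in the authors' deposited tables. Targets of p53 (median 1.16, 15 of 16), immediate early genes (0.91, 12 of 20), cell cycle genes (0.84, 20 of 22) and genes of the mitochondrial genome (0.37, 4 of 4) were also higher in axons. Presynaptic genes (-1.59, 0 of 37), postsynaptic genes (-1.36), axonal cytoskeleton genes (-1.35, 4 of 42) and markers of other neurons (-2.23, 0 of 15) were lower there, with the tubulin Tubb3 at 183 FPKM in axons and 675 in cell bodies and the growth cone protein Gap43 at 174 and 697 FPKM in the authors' deposited tables. Microglia markers (-2.80), oligodendrocyte markers (-1.36), small noncoding RNAs (-1.30), axon guidance genes (-0.97), nuclear long noncoding RNAs (-0.84), respiratory chain genes (-0.82), histones (-0.79), motoneuron disease genes (-0.73) and motoneuron markers (-0.72) also lay below the median of all genes, -0.60 over 17332. Endothelial markers (-0.58), the 7SK particle (-0.55), cholesterol synthesis (-0.55), the hnRNP family (-0.54), splicing factors (-0.50), astrocyte markers (-0.47), translation factors (-0.24), the unfolded protein response (-0.11), ribosomal proteins (0.09) and interferon genes (0.10) lay above it. The side of several lists turned with the setting. With 1 FPKM added the median of all genes was -0.38, and the 7SK particle (-0.52), cholesterol synthesis (-0.52), the hnRNP family (-0.53), splicing factors (-0.49) and astrocyte markers (-0.44) lay below it and motoneuron markers (-0.37) above. Among genes at 1 FPKM or more motoneuron markers (-0.53) lay above the median of -0.58 and endothelial markers (-3.25) below it. Actb was at 2210.3 FPKM in axons and 1322 in cell bodies, and Rn7sk at 2638 and 9892 FPKM, in the authors' deposited tables. Chat, Mnx1 and Isl2, markers of motoneurons, were listed at 0 in both. The tables were normalized separately, so these are levels set side by side with 0.1 FPKM added, without a test. RNA of other cells on the axonal side was not told apart from RNA of motoneuron axons.

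7SK was the RNA most often crosslinked to hnRNP R in every hnRNP R library that was not a nuclear fraction. Rn7sk (mm9 chromosome 9, 78023109 to 78023439) took 1.26% (95% interval 1.22 to 1.30) and 1.01% (0.980 to 1.05) of cDNAs in both unfractionated motoneuron libraries and 2.54% (2.49 to 2.58) and 7.35% (7.19 to 7.51) in both NSC34 libraries, against 0.127% (0.0928 to 0.169) with IgG. Cytoplasmic fractions held 1.19% (1.14 to 1.24) in motoneurons, 26.8% (25.3 to 28.3) in NSC34 cells with antibody 1 and 12.7% (11.5 to 14.0) with antibody 2. Nuclear fractions held 0.110% (0.0891 to 0.133), 0.386% (0.333 to 0.446) and 0.267% (0.163 to 0.412) in the same order. Intervals are exact Clopper-Pearson and cover counting error only. A share also depends on the other RNAs of its library. Introns held 26.4% and 43.0% of cDNAs in the cytoplasmic NSC34 libraries (antibodies 1 and 2) and 91.8% and 91.6% in the nuclear ones. These cytoplasmic libraries held only 3569 and 2796 cDNAs. The cytoplasmic motoneuron library held 87.5% of its cDNAs in introns, near the 88.1% and 86.5% of the unfractionated motoneuron libraries. In the edgeR quasi-likelihood test 7SK was higher in NSC34 cells than with IgG (log2 ratio 5.57, SE 0.50, Benjamini-Hochberg adjusted p = 1.92e-13; 18927 cDNAs in 2 libraries against 46, a depth-scaled ratio of 26.8 with a counting interval of 20.1 to 36.7). With each crosslink position counted once, a count that the length of the gene bounds, the ratio against IgG was -0.37 (edgeR adjusted p = 0.797). By cDNAs 7SK was lower in motoneurons than in NSC34 cells (log2 ratio -1.19, SE 0.29, edgeR Benjamini-Hochberg adjusted p = 0.000489). This log2 ratio was -0.35 without NSC34 replicate 2 and -2.13 with library size alone (edgeR adjusted p = 2.04e-13). By DESeq2 it was not past the threshold (-1.21, adjusted p = 0.347). The nuclear to cytoplasmic log2 ratio of 7SK was -4.27 (SE 1.95, edgeR Benjamini-Hochberg adjusted p = 1 over 3 pairs), past the threshold by DESeq2 (-4.78, adjusted p = 0.00214) and by edgeR without the motoneuron pair (-5.33, adjusted p = 1.01e-12). Other annotated 7SK copies, whose reads cannot be told from Rn7sk with certainty, held 4.09% to 25.8% of all 7SK cDNAs per library.

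**Figure D3:**
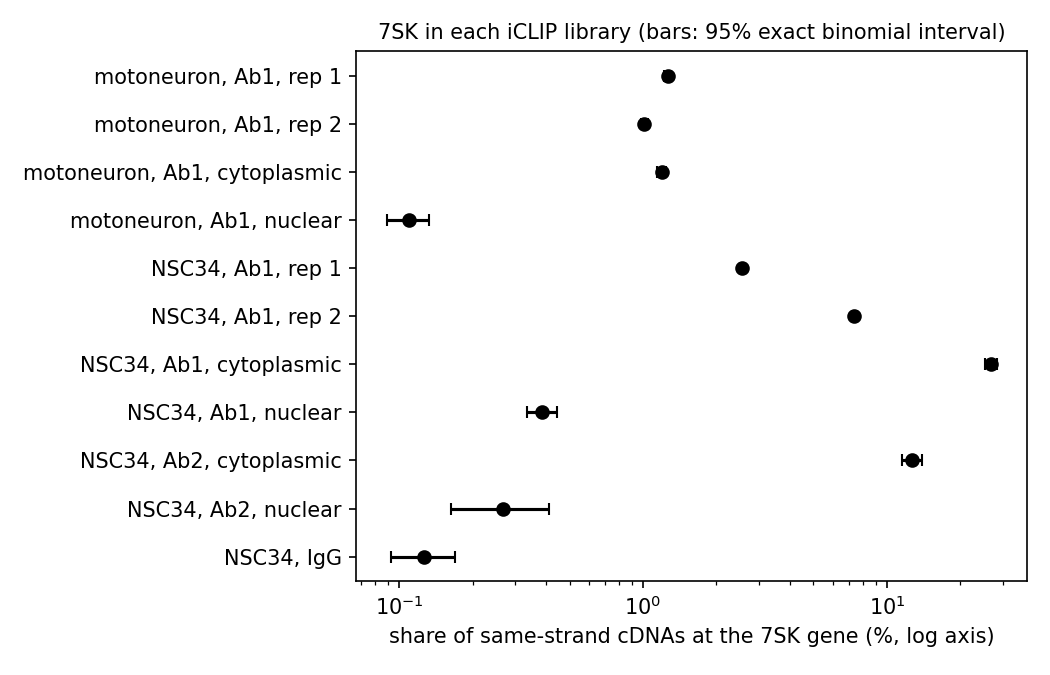
Share of cDNAs on 7SK (percent, log axis) in each of the 11 iCLIP libraries, points with exact 95% binomial intervals. The cytoplasmic NSC34 libraries stood at 26.8% and 12.7%, the nuclear ones at 0.386% and 0.267% and IgG at 0.127%. A share depends on the other RNAs of its library, and the cytoplasmic NSC34 libraries held only 3569 and 2796 cDNAs.

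Against IgG, hnRNP R in NSC34 cells was enriched on 19 genes and depleted on 32 of 9567 by the edgeR quasi-likelihood test. Only 11 of these (3 higher, 8 lower) were called by DESeq2 and 11 (3 and 8) by the bias-adjusted edgeR fit, while a fit of the NSC34 and IgG libraries alone called 187 genes, 50 of these among them. Beside 7SK and its copy Gm23037 (233 against 2 cDNAs, ratio 7.60 with a counting interval of 2.08 to 63.1), the mitochondrial ribosomal RNAs AY172335.9 (log2 ratio 2.90) and AY172335.12 (2.58) and the Y RNA Rny3 (2.48, edgeR adjusted p = 3.89e-05) were higher, Rny3 as the only call of its list, over all genes and adjusted over the list alone. Snap25, a SNARE of synaptic vesicle fusion, was higher with 405 against 5 cDNAs (log2 ratio 2.67, SE 0.54, edgeR Benjamini-Hochberg adjusted p = 0.00226), and Rtn3 (195 against 2 cDNAs, ratio 6.36, counting interval 1.74 to 52.9) and the splicing factor Rbm39 (254 against 3, ratio 5.52, interval 1.87 to 26.9) were higher too. AL731552.1 (149 against 1, ratio 9.71, interval 1.72 to 386), Pus10 (132 against 0, at least 2.87-fold higher over the group with a floor of 3 counts) and Ap1s2 (101 against 0, at least 2.19-fold) completed the 10 highest. Lower than with IgG were Neto2 (3 against 5 cDNAs, inverse ratio 25.6, interval 4.97 to 165), the dynein light chain Dynll2 (log2 ratio -3.46), the chaperone Hsp90ab1 (-2.95), Unc13a, which primes synaptic vesicles (-2.94), Rara (-2.44) and the unnamed loci AC091681.1, AC123039.1, AC152059.1, AL928940.1 and mmu-mir-689-2 (-3.88, -2.91, -2.83, -2.76 and -2.64). Of list members, Eif4g2 was higher (1.92, edgeR adjusted p = 0.0416) and the nuclear RNA Neat1 lower (-2.22, edgeR adjusted p = 0.0260). Presynaptic genes gave 3 higher and 4 lower adjusted over the list alone, and no list was enriched among the calls (lowest Benjamini-Hochberg adjusted p = 0.129 by Fisher's exact test, nuclear long noncoding RNAs). An unadjusted p under 0.05 gave 597 higher and 390 lower genes. With library size alone the split was 10 higher and 71 lower and the median log2 ratio moved from 0.36 to 0.08. Without NSC34 replicate 2 the test called 6 genes, and IgG had 1 library, so its own spread was not measured.

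The cDNA counts of hnRNP R iCLIP differed between motoneurons and NSC34 cells: 2237 genes were higher and 1329 lower in motoneurons among 9567 tested by edgeR. There was no IgG library of motoneurons, and the counts were not set against the RNA levels of both cell types, so a difference in contact was not tested apart from a difference in RNA. The list members named here were chosen after their values were seen. Fisher's exact test took genes as independent and matched the lists on neither cDNA count nor locus span. In simulated data of this design 67.0% of changes of 2 on the log2 scale were recovered, and 100% among genes with at least 100 cDNAs. Lists of long or strongly counted genes can thus hold more calls for that reason alone. Postsynaptic genes were higher for 19 of 21 tested, also 19 adjusted over the list alone (edgeR calls, one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 4.17e-09), such as the glutamate receptor Grm5 (2457 against 4 cDNAs, log2 ratio 9.80) and the adhesion molecule Nlgn1 (3089 against 9, 8.98). Axon guidance genes were higher for 29 of 38, 30 adjusted over the list alone (Fisher's exact adjusted p = 4.93e-10 among edgeR calls), with the receptor phosphatase Ptprd (5512 against 10, 9.70), the netrin receptor Dcc (1430 against 9, 7.94) and the Slit receptor Robo2 (1645 against 13, 7.60). Presynaptic genes were higher for 21 of 33, 25 adjusted over the list alone (adjusted p = 2.09e-05 for the edgeR calls), among them the adhesion gene Nrxn3 (2855 against 15, 8.24). Axonal cytoskeleton genes were higher for 20 of 38, 21 adjusted over the list alone (adjusted p = 0.00146 for the edgeR calls), with Dclk1 (971 against 57, 4.76) and the tau gene Mapt (273 against 95, 2.24). Markers of other neurons were higher for 6 of 7, also 6 adjusted over the list alone (adjusted p = 0.0124 for the edgeR calls). Lower in motoneurons were 14 of 19 cell cycle genes (adjusted p = 3.74e-07 for the edgeR calls; Top2a 4 against 160, -4.56), 6 of 7 genes of the mitochondrial genome (adjusted p = 0.00149; mt-Cytb 43 against 493, -2.69) and 6 of 8 small noncoding RNAs (adjusted p = 0.00351; Rny3 567 against 4264, -2.84). Translation factors (12 of 29, adjusted p = 0.00439; Pabpc1 17 against 99, -1.86) and motoneuron markers (6 of 9, adjusted p = 0.00557; Ret 10 against 291, -4.13) were lower too by the edgeR calls. Adjusted over the list alone the lower counts were 14 for the cell cycle, 7 for the mitochondrial genome, 6 for small noncoding RNAs, 12 for translation factors and 7 for motoneuron markers. No other list was enriched, among them splicing factors (4 higher and 4 lower of 34, or 1 and 12 with library size alone), ribosomal proteins (0 and 5 of 48, or 0 and 16) and respiratory chain genes (0 and 7 of 53, or 0 and 23). With library size alone the lower calls also covered 21 translation factors, 17 cell cycle genes, 7 genes of the mitochondrial genome, 7 small noncoding RNAs and 7 motoneuron markers.

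For genes with no cDNA on 1 side only a lower bound of the ratio between the cell types can be given. Higher in motoneurons by at least 263-fold was Egfem1 (962 against 0), by at least 149-fold the microtubule protein Dcx (546 against 0 cDNAs), by at least 144-fold the potassium channel Kcnma1, and by at least 136-fold Hecw1. The next were by at least 134-fold the glutamate receptor Grm3, by at least 118-fold Gria1, by at least 107-fold the calcium channel Cacna1d and by at least 96.8-fold Nav2. Odz2, a teneurin, had 3322 against 2 cDNAs (ratio 1363, counting interval 377 to 11256) and the neurexophilin Nxph1 1365 against 1 (ratio 1120, interval 201 to 44258). Lower by at least 70.7-fold was Grid2ip, by at least 66.6-fold the retinol transporter Stra6, by at least 49.2-fold Emid1, by at least 42.3-fold Pir and by at least 37.4-fold Nxf3. Lower by at least 31.3-fold was Hmmr, by at least 30.1-fold the co-chaperone Bag3, by at least 29.7-fold Mrvi1, by at least 27.6-fold Gch1 and by at least 26.0-fold Traf3ip2. Of these 10, Grid2ip, Stra6, Emid1, Pir, Hmmr and Mrvi1 had higher depth-scaled counts in the IgG library than in either NSC34 library. Grid2ip stood at 827 cpm with IgG against 311 and 321. Scaled to depth, their NSC34 values thus did not exceed those of the lone IgG library. Beside 7SK, the most crosslinked genes of unfractionated motoneurons included Cntnap2, Ptprd, Lingo2, Nrg3, Cadm2, Pcdh9, Meg3 and Malat1. With library size alone 1343 genes were higher and 3554 lower and the median log2 ratio moved from 0.08 to -0.86. The higher calls then numbered 25 of 38 axon guidance, 17 of 21 postsynaptic, 12 of 33 presynaptic and 12 of 38 axonal cytoskeleton genes. Genes of the hnRNP family went from 3 higher and 3 lower to 0 and 16 and cholesterol synthesis genes from 5 higher and 0 lower to 0 and 4. Without NSC34 replicate 1 the edgeR test called 1954 genes, and DESeq2 called 1497.

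Between nuclear and cytoplasmic fractions the edgeR quasi-likelihood test with pairs called 0 of 5177 genes, with 27 at an unadjusted p under 0.05 (8 higher and 19 lower in nuclei), and DESeq2 called 3, all lower in nuclei. The Y RNAs Rny1 (log2 ratio -8.77) and Rny3 (-4.81) and the mitochondrial genes mt-Nd5 (-6.33) and mt-Co1 (-5.65) had the lowest values of their lists and the small nucleolar RNA Snord118 (6.44) the highest, none past the threshold over all genes (edgeR Benjamini-Hochberg adjusted p = 1). Adjusted over the list alone, 3 of 6 genes of the mitochondrial genome were lower and of 3 small noncoding RNAs 1 was higher and 2 were lower in nuclei. Without the motoneuron pair the edgeR test called 6 genes, all lower in nuclei, and in simulated data of this design it recovered 0% of changes of 4 on the log2 scale. The cytoplasmic NSC34 libraries held 3569 and 2796 cDNAs, and the median log2 ratio was 0.67, or 0.28 with library size alone. The cytoplasmic motoneuron library correlated across genes with the unfractionated motoneuron libraries at Pearson 0.878 and 0.885. It held 87.5% of its cDNAs in introns, and how far it was free of nuclear RNA was not tested.

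Unfractionated replicates resembled one another across genes with Pearson 0.889 in motoneurons (6319 genes) and 0.796 in NSC34 cells (7225 genes), on log2 depth-scaled cDNA counts, and differed by more than sampling noise (chi-square per degree of freedom 3.08 and 2.28). Both antibodies gave 0.259 in nuclear NSC34 fractions (1482 genes) and 0.255 in cytoplasmic ones (21 genes). The NSC34 replicates gave 0.563 and 0.426 against IgG, and a motoneuron replicate against an NSC34 replicate gave 0.0292 to 0.221. Genes are not independent replicates, and the shared level of a gene adds to each of these values.

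Genes most crosslinked to hnRNP R, the top 10% by motoneuron cDNAs per FPKM, stood lower than others in axons after hnRNP R knockdown. Their median log2 ratio was -0.14 over 163 genes against 0.15 over 1470 others, a difference of -0.29 at percentile 0.03 of random sets matched on FPKM. The difference was 0.08 (percentile 76.8) in the axon group labelled 7SK knockdown, 0.06 (percentile 95.4) on the somatodendritic side after hnRNP R knockdown and -0.03 (percentile 5.74) there after 7SK knockdown. The most crosslinked genes per FPKM on the somatodendritic side included the adhesion genes Lingo2 (5117 cDNAs), Ptprd (5512), Cadm2 (4665) and Cntnap2 (5666), none of which passed after hnRNP R knockdown in the authors' deposited table. Set against genes with no cDNA, the difference was -0.70 in hnRNP R axons, -0.41 in the axon group labelled 7SK knockdown and -0.32 in 7SK cell bodies, each at percentile 0 of permutations within FPKM bins, and -0.029 in hnRNP R cell bodies (percentile 4.18). By cDNAs alone it was -0.17 in hnRNP R axons (percentile 0.17), -0.095 in the axon group labelled 7SK knockdown (percentile 16.96), 0.05 in hnRNP R cell bodies (percentile 96.785) and -0.15 in 7SK cell bodies (percentile 0). Among these settings a drop in hnRNP R axons alone thus held only with the first. With locus span matched too, the percentile was 0.53 in hnRNP R axons and 100 in the axon group labelled 7SK knockdown. It was 96.48 in hnRNP R cell bodies and 64.65 in 7SK cell bodies. In the latter, 52 of the 182 genes lay in bins with fewer comparison genes than members, so that match was poorer. The mean FPKM of the ranking includes the knockdown value, which favours genes that fell. Names matched for 91.0% to 94.5% of the tested genes.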

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

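The comparison of antisense shares with IgG was among the tests chosen only after the data were seen; the tests of a difference between compartments were planned.

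Smooth muscle actin Acta2 differed between compartments of the 7SK groups. It fell by 1.62 on the log2 scale in the axon group labelled 7SK knockdown and rose by 0.77 on the somatodendritic side in the authors' deposited tables, a difference of -2.39 (SE 0.443, Benjamini-Hochberg adjusted p = 5.80e-05 by the z test). Igfbp2, which binds insulin-like growth factors, had -1.62 and 0.95 (difference -2.57, SE 0.587, adjusted p = 0.00358) and tropomyosin Tpm1 had -1.36 and 0.34 (difference -1.70, SE 0.386, adjusted p = 0.00358), by the same z test with Benjamini-Hochberg. The axonal kinesin Kif1a had 1.04 in axons and -0.49 on the somatodendritic side (difference 1.53, SE 0.406, adjusted p = 0.0372, Benjamini-Hochberg). Igfbp2, Tpm1 and Kif1a each passed in 1 compartment and not in the other. With standard errors from the authors' test statistic none of the 888 genes passed, and 3 had an unadjusted p under 0.05. Acta2 belongs to the fibroblast list, which moved the same way: its summed FPKM was 1624 and 915 in the axon comparison (median log2 ratio -0.58, percentile 2.29) and 249 and 367 on the somatodendritic side (0.53, percentile 98.1) in the authors' deposited tables. A change in the share of such cells was not separated from a change within cells by any test.

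Antisense cDNAs, which the comparisons of the report leave aside, had a larger share in each fractionated NSC34 library than in the IgG library, with 1 library per group and intervals that cover counting error only. IgG held 5.51% (95% interval 5.28 to 5.74). Cytoplasmic NSC34 libraries held 8.35% (7.50 to 9.26) with antibody 1 and 12.1% (11.0 to 13.3) with antibody 2, and nuclear ones 6.16% (5.96 to 6.37) and 8.79% (8.19 to 9.42). Unfractionated NSC34 libraries (4.30% and 4.78%) and motoneuron libraries (2.11% to 4.08%) lay below IgG. Replicates of unfractionated motoneurons held 3.15% and 2.11%, further apart than the nuclear antibody 1 library and IgG, so that gap is no larger than one between replicates.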

How the results depend on the processing

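The bias-adjusted edgeR tests, the lists matched on locus span and the permutation against genes with no cDNA were chosen only after the results were seen, and the other tests of this part were planned. Of 133 alternatives 96 kept the direction and the side of the threshold or stayed within the limit for a count, 26 moved, 3 were weaker, 4 stronger and 4 reversed. Where no reason is given, the cause was not tested.

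At an unadjusted p under 0.05 the authors' tables held 162 genes in axons and 340 on the somatodendritic side for hnRNP R and 183 and 299 for 7SK, with 36 shared in axons and 52 on the somatodendritic side. At q under 0.01 there were 0 genes in hnRNP R axons, 19 in the axon group labelled 7SK knockdown and 16 in hnRNP R cell bodies. An absolute log2 ratio of at least 1 left 6 genes after hnRNP R and 19 after 7SK knockdown in cell bodies. Standard errors from the authors' test statistic gave 0 genes whose 7SK effect differed between compartments. Control values of the 7SK tables gave a mitochondrial genome median of 0.53. The filter at 1 FPKM removed no tested gene and so moved nothing in these tables. No paired analysis was possible because the RNA tables hold group values only.

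Against IgG, library size alone gave 81 genes, DESeq2 11, crosslink positions 24, the bias-adjusted fit 11, and a fit of only the NSC34 and IgG libraries 187. Leaving out 1 NSC34 library gave 6 (without replicate 2) to 38 (without replicate 1), the lone library left being assumed to vary like the others. Motoneurons against NSC34 cells gave 1497 genes by DESeq2 and 1954 (without NSC34 replicate 1) to 3106 on leaving out 1 library. With library size alone it gave 4897, split 1343 higher and 3554 lower.

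Nuclear against cytoplasmic fractions gave 1 gene with DESeq2 size factors, 1 with library size alone, 3 by DESeq2, 1 at a minimum of 50 cDNAs and 0 to 6 (without the motoneuron pair) on leaving out a pair. The replicate block gave 3211 genes between motoneurons and NSC34 cells and a 7SK log2 ratio of -1.02, although replicate numbers did not pair these libraries (Pearson -0.00681), and without the block for pairs the fractions gave 0 genes.

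For 7SK, counting each crosslink position once reversed the log2 ratio against IgG to -0.37 (101 and 96 positions in the NSC34 libraries, 31 in IgG) and gave -0.15 between motoneurons and NSC34 cells. DESeq2 gave -1.21 between the cell types, no longer past the threshold, and -4.78 between fractions, past it. Library size alone gave -2.13 between the cell types. Leaving out 1 library gave 4.61 to 6.05 against IgG and -1.94 to -0.35 between the cell types, the latter without NSC34 replicate 2. Leaving out a pair gave -5.33 (without the motoneuron pair, past the threshold with an edgeR adjusted p = 1.01e-12) to -4.04 between fractions.

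For crosslinked genes, the top 10% by cDNAs reversed the difference to -0.095 in the axon group labelled 7SK knockdown (percentile 16.96). Genes with no cDNA as the comparison reversed it to -0.41 there and to -0.029 after hnRNP R knockdown in cell bodies. After 7SK knockdown in cell bodies it was -0.32 with that comparison and -0.15 with the top 10% by cDNAs, both past the threshold. Fewer genes had no cDNA than stood in the top set, so membership was permuted within FPKM bins for that comparison. Matching on locus span as well left 21 lists outside the central 95%. Single positions and bins for the agreement of libraries were not run, because counts came per gene. The cytoplasmic NSC34 libraries held 2796 and 3569 cDNAs. In simulated data with the spread of the fractions (dispersion 0.582) edgeR recovered 0% of changes of 4 on the log2 scale also among the 31 changed genes with at least 100 cDNAs.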

Other observations

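The tests of microglial RNA, of the authors' scaling, of the shared control libraries and of other splits were chosen only after the results were seen. The tests of gene length, taken as locus span, were written before.

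Larp7, the La-related protein that binds 7SK, was listed at 4.65 and 1.27 FPKM on the somatodendritic side after hnRNP R knockdown and at 6.65 and 2.40 FPKM in axons, untested and chosen after its values were seen, in the authors' deposited tables. In the 7SK groups Larp7 stood at 4.28 and 5.09 FPKM on the somatodendritic side and 6.85 and 8.08 FPKM in axons in the authors' deposited tables. The class I molecule H2-K1, which rose in cell bodies after both knockdowns, had log2 ratios of 0.68 (q = 0.631) in hnRNP R axons and 0.61 (q = 0.385) in the axon group labelled 7SK knockdown in the authors' deposited tables. The nuclear RNA Malat1 was at 650.4 and 715 FPKM (q = 0.856) in cell bodies and at 335 and 288 FPKM (q = 0.906) in axons after hnRNP R knockdown in the authors' deposited tables.

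Introns held most hnRNP R cDNAs in nuclei, 91.5% in motoneurons and 91.8% and 91.6% in NSC34 cells with antibodies 1 and 2. Cytoplasmic fractions held 87.5% in introns in motoneurons and 26.4% and 43.0% in NSC34 cells, and IgG 76.2%. Meg3, a long noncoding RNA kept in nuclei, led the nuclear motoneuron library with 762 cDNAs (0.835%), and had 4041 cDNAs in unfractionated motoneurons against 6 in NSC34 cells (log2 ratio 9.97, edgeR Benjamini-Hochberg adjusted p = 2.85e-32). Neat1, the scaffold of paraspeckles, had 9 against 77 (log2 ratio -2.18, edgeR adjusted p = 0.00129). These were named after their values were seen.

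Gpnmb and Spp1, which macrophages express, were higher in the axon group labelled 7SK knockdown, where Rn7sk itself was not lower. The median of the microglia list, written before the data were examined and holding no gene called over all genes, lay at percentile 100 of random lists matched on FPKM. RNA of microglia may have entered these axon libraries, but more microglia or a change of expression within the cultures would give the same value. Tyrobp stood at 0.886 and 43.0 FPKM, Lyz2 at 2.64 and 29.4, C1qa at 1.09 and 21.4 and Trem2 at 0 and 18.4 in the authors' deposited table, while 12 of 15 list genes were at 1 FPKM or more in control cell bodies. A common shift of all tested genes was argued against, since their median log2 ratio was 0.23, below the smallest called increase. A scaling that centres the tested genes would give a low median in any case, so the authors' scaling was not excluded. Which of these holds stays open, as no test separated them.

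Ribosomal protein and respiratory chain genes stood high in hnRNP R knockdown axons and in the axon group labelled 7SK knockdown. With random lists matched on locus span as well as FPKM the lowest of the 4 percentiles was 99.35. Locus span includes introns and was matched in 4 bins, and transcript length was not matched, so gene length as a cause stays open. Chance values of the control axon libraries, which both comparisons share, cannot be told apart from an effect of the treatments, because the controls could not be split, and the lower of both axon medians of ribosomal genes was 0.61. A response of axonal RNA common to both treated groups may also lie behind it and was not tested. Rn7sk itself was not lower in the axon group labelled 7SK knockdown.

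Genes most crosslinked to hnRNP R stood lower in axons after hnRNP R knockdown. Their median lay at percentile 0.53 of random sets matched on FPKM and locus span. Span was matched in 4 bins only, and the median span was 154527 bases in the set and 23206 in other genes. Gene length as a cause thus stays open. The ranking also divided by a mean FPKM that includes the knockdown value, which favours genes that fell. Set against genes with no cDNA, by a permutation matched on FPKM but not on locus span and chosen after the results were seen, the most crosslinked genes were also lower in the axon group labelled 7SK knockdown (-0.41) and in 7SK cell bodies (-0.32). A loss of hnRNP R from its target RNAs stays open and was not tested. With the same matching the set lay at percentile 100 in the axon group labelled 7SK knockdown, where FPKM matching alone gave 68.0.

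For nuclear against cytoplasmic libraries, 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 0 genes, a count that any split reaches, and the highest of the others 1.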
